A study of Homo sapiens with 12 samples.

How the data were processed

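RNA from 12 samples of the RKO colon carcinoma line was measured, 1 array per sample, with 3 arrays in each of 4 groups: control siRNA with vehicle, control siRNA with HNE, HSF1 siRNA with vehicle and HSF1 siRNA with HNE. Per the labels, treatment was 50 µM HNE or 0.5% DMSO for 6 h, RNA was extracted with Trizol and an RNeasy column, amplified in 2 rounds by single-primer isothermal amplification, and labelled with biotin for an Affymetrix gene array. The deposited values are log2 RMA summaries per probe set, made by the authors with Affymetrix Expression Console, whose version is not given. RMA stands for background correction, quantile normalization between arrays and a median polish over probes. The scale was checked on the values, which ran from about the same minimum to the same maximum in every array with medians of 5.6 to 5.69. Scanner files were not analysed, so background correction and any scanning batches were not examined. The number of arrays limits the precision.

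The table held 33297 probe sets. The annotation paired 19460 of them with 1 gene symbol, 1754 with several and 12083 with none, and symbols were brought to current names through the reference gene table, which matched 19429 of the single-symbol probe sets by gene identifier. Genes were tested on single-symbol probe sets, and for the 769 genes with several the one with the highest mean over the 12 arrays was used, which gave 18417 genes. No gene was left out for low signal. As a measure of background, the 95th percentile of the means of 361 olfactory receptor genes, log2 5.35, was used, and 11571 genes lay above it. HSPA1A and HSPA1B share all their probe sets on this array and were read from the 5 probe sets listed with both.

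Group means were fitted with limma 3.58.1 in R 4.3.3 over all 12 arrays, with 8 residual degrees of freedom and moderated variances. The 5 comparisons were HNE against vehicle in control cells, HNE against vehicle in silenced cells, HSF1 siRNA against control siRNA with vehicle and with HNE, and the difference between the HNE responses (silenced minus control). Benjamini-Hochberg adjustment ran over the 18417 genes of each comparison, and genes with an adjusted p under 0.05 were called. The HSF1 transcript was also compared by an exact two-sided permutation test. The HNE responses of the control and silenced cells were compared across genes by Pearson's and Spearman's correlation and by the overlap of called genes against that of independent lists.

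There were 23 gene lists, fixed before the data were examined, as were the list tests and the naming rule: heat shock chaperones, BAG family, BCL2 family, NRF2 antioxidant and glutathione genes, aldehyde metabolism, unfolded protein response, ATF4 and amino acid response, p53 targets, immediate early genes, NF-kB targets, interferon-stimulated genes, DNA replication, mitosis, replication-dependent histones, proteasome subunits, ubiquitin and autophagy receptors, metallothioneins and metal transport, cholesterol synthesis, ribosomal proteins, heat shock factors, and markers of colon epithelium, fibroblasts and leukocytes. Of 506 entries 463 were measured, and 43 were not analysed here because no probe set was paired with that symbol alone. Lists were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists of a comparison, with an estimated correlation and with fry beside it. Named genes were, per comparison of groups, the 12 largest rises and 8 largest falls among called genes whose 3 arrays of one group all lay above the 3 of the other, leaving out uncharacterized loci and small RNAs. For the difference between the HNE responses they were the 10 most positive and the 10 most negative. Added to these were up to 4 members with the smallest p per list, any member of the chaperone, BAG, BCL2, NRF2 and heat shock factor lists, and HSF1, BAG3, HSPA1A, HSPA1B, DNAJB1, HMOX1, BCL2L1, MCL1 and BCL2.

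The fit was tested on simulated data with 50 planted genes per size. For a comparison of groups it recovered 76% of changes of log2 0.5, 100% of changes of log2 1 and 96% of changes of log2 2, with 8 false calls among 194. For a difference between responses it recovered 38%, 92% and 100%, with 10 false calls among 175. The simulated noise was independent between genes and few genes were changed. The data hold more changed genes and an intensity trend, so these rates may not carry over to them. Alternatives were a replicate block, the 6 arrays of a comparison alone, dim genes left out, all probe sets, the mean of a gene's probe sets, quantile normalization applied again, arrays centred on their medians, a trended and robust variance, array weights, a 2-fold threshold, and each array left out in turn. Cyclic loess between arrays was added after an intensity trend had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.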

Results

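Gene expression was measured in RKO cells, an established human colon carcinoma line, on 12 Affymetrix arrays. Cells were transfected with a small interfering RNA (siRNA) against HSF1, the transcription factor that drives heat shock genes, or with a control siRNA. They were then treated for 6 h with 50 µM 4-hydroxynonenal (HNE), an electrophilic aldehyde formed when membrane lipids are oxidised, or with vehicle, 0.5% DMSO. The 4 groups held 3 arrays each. The question posed by the design was which transcripts HNE changed, and which of those changes differed when HSF1 was silenced. The deposited RMA values on the log2 scale had medians between 5.6 and 5.69 over the 12 arrays. Correlations between arrays ran from 0.990 to 0.996 within groups and from 0.979 to 0.994 between groups. In all, 18417 genes were tested, and 62.8% of them had a mean above the background level set by olfactory receptor genes. The labels describe the samples as triplicates but do not say whether they came from separate cultures, so p-values measure the spread between these samples, which may be technical. Changes are given as log2 differences ± standard error (SE) from a fit over 4 groups with n = 3 each, and p-values are adjusted for the 18417 genes of a comparison.

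HSF1 transcript itself was lower in the silenced cells under both treatments. Its probe set, 8148824, had a mean of 7.05 ± 0.05 (SD, n = 3) in control vehicle arrays and 6.51 ± 0.14 (SD, n = 3) in silenced vehicle arrays. With HNE the means were 6.99 ± 0.02 (SD, n = 3) and 6.5 ± 0.14 (SD, n = 3). HSF1 signal thus fell by 0.54 ± 0.09 with vehicle, to 68.8% of control (limma, adjusted p = 0.00753), and by 0.49 ± 0.09 with HNE, to 71.0% of control (adjusted p = 0.0012). With means this near the background level of 5.35, these ratios may understate the fall of the transcript. HSF1 protein is not measured by these arrays. The highest silenced array lay at 6.64 with vehicle and 6.6 with HNE, and the lowest control array at 7.00 and 6.98. An exact two-sided permutation test of 3 against 3 arrays gave p = 0.1 under each treatment, the smallest p that this design allows. HNE left no called change in HSF1, with -0.05 in control cells and -0.01 in silenced cells. None of the 5 measured genes of the heat shock factor list was called by limma with HNE in either siRNA group, and 0 had an unadjusted p under 0.05. With the HSF1 siRNA under HNE, HSBP1, which encodes a protein that binds HSF1, also fell by 0.37.

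**Figure D1:**
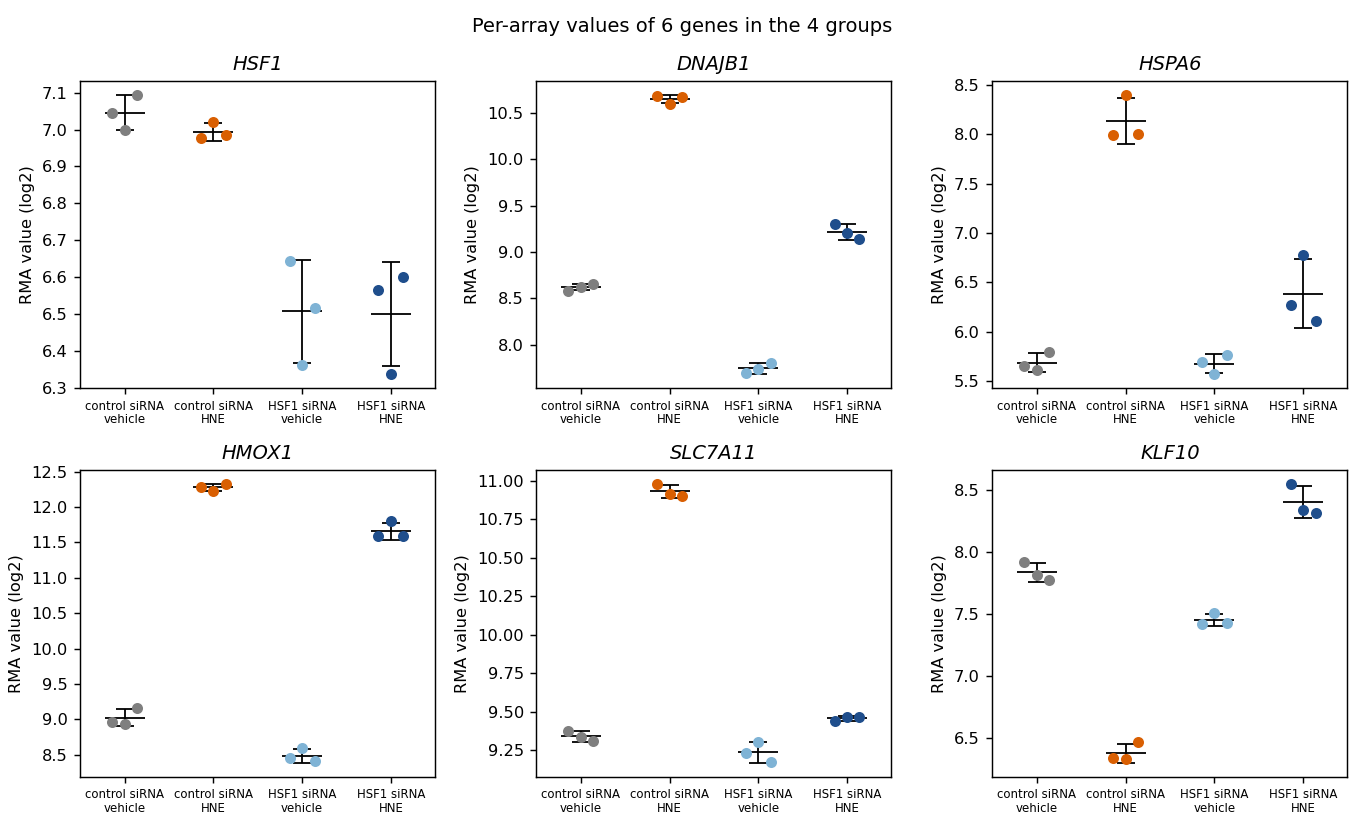
Per-array RMA values (log2, vertical axes with a separate range per panel) of HSF1, DNAJB1, HSPA6, HMOX1, SLC7A11 and KLF10 in the 4 groups. Points are single arrays, horizontal marks are group means and bars are the SD of 3 arrays. HSF1 lies between 6.34 and 6.64 in silenced cells and at 6.98 or above in control cells, SLC7A11 is at 10.93 in HNE-treated control cells and at 9.46 in HNE-treated silenced cells, and KLF10 moves down with HNE in control cells and up in silenced cells.

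In control cells, HNE raised heat shock chaperones, glutathione and antioxidant genes and ubiquitin and autophagy receptors, and it lowered mitotic, DNA replication and histone genes. The steepest rise was that of ZFAND2A, an arsenite-inducible protein that associates with the proteasome, at 3.80 ± 0.06 or 13.9-fold (adjusted p = 5.21e-13). It was followed by HMOX1, heme oxygenase 1, at 3.26 ± 0.08 or 9.55-fold (adjusted p = 1.14e-10). Among the 18417 genes, 3102 changed, 1788 higher and 1314 lower, and 139 of them by at least 2-fold. Among the single-symbol genes open to the naming rule, the largest rises after these were in HSPA6 (2.44), DNAJB4 (2.42), ACTRT3 (2.34), HSPA1L (2.10), DNAJB1 (2.02), CRYAB (1.99), DNAJA4 (1.97), EID3 (1.90), the collagen prolyl hydroxylase P4HA2 (1.89) and GCLM (1.83). The mean of CRYAB over the 12 arrays, 4.34, lay below the background level of 5.35, and it reached 5.67 ± 0.27 (SD, n = 3) with HNE in control cells. The largest falls were those of the linker histone H1-3 (-1.98), E2F8 (-1.90), the mitotic kinase PLK1 (-1.55), MAP1LC3C (-1.54), H2BC14 (-1.5), the kinesins KIF18A (-1.47) and KIF20A (-1.40), and KLF10 (-1.45).

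Of 29 measured heat shock chaperone genes, 19 rose with HNE in control cells and none fell, and 19 rose when adjusted over the list alone (camera, adjusted p = 1.7e-19). The list members named above were HSPA6, HSPA1L, DNAJB1, DNAJB4 and CRYAB, while DNAJA4 is not in the list and is not counted in it here or below. Besides these members, HSPA4L rose by 1.32, BAG3 by 1.39, HSPH1 by 1.02, SERPINH1 by 0.74, HSPB1 by 0.74, DNAJB6 by 0.65, DNAJB2 by 0.63, HSPA4 by 0.60 and STIP1 by 0.50. DNAJA1, CCT4, CACYBP, FKBP4 and TCP1 rose by 0.23 to 0.32. HSPA1A and HSPA1B, the stress-inducible HSP70 pair, cannot be told apart on this array, and the 5 probe sets listed with both rose by 2.06 to 2.83. Of these, probe sets 8178086 and 8179324 had the same values. Whether HSPA1L shares signal with this pair was not examined. In the BAG family, a group of HSP70 cochaperones, BAG3 was the only one of 6 called, while 3 were higher when adjusted over the list alone.

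The NRF2 list of antioxidant and glutathione genes had 13 of 29 measured members higher with HNE in control cells, 14 when adjusted over the list alone, and none lower (camera, adjusted p = 5.27e-11). Next to HMOX1 and GCLM, the regulatory subunit of glutathione synthesis, the cystine transporter SLC7A11 rose by 1.59, SRXN1 by 1.34, ferritin light chain FTL by 1.27, TXNRD1 by 1.05, NQO1 by 0.79, OSGIN1 by 0.65 and GCLC by 0.56. Among ubiquitin and autophagy receptors, 11 of 18 rose and 16 when adjusted over the list alone (adjusted p = 5.43e-11), among them GABARAPL1 by 1.52, WIPI1 by 0.62 and MAP1LC3B by 0.55. Cholesterol synthesis had 9 of 15 members higher, and 9 when adjusted over the list alone (adjusted p = 2.71e-07), including HMGCS1 at 1.46, INSIG1 at 1.39, IDI1 at 0.78 and SC5D at 0.77. In the ATF4 and amino acid list 9 of 28 rose and 3 fell, against 9 and 5 when adjusted over the list alone (adjusted p = 0.00547). CTH rose by 1.65, PPP1R15A by 1.46 and DDIT3 by 1.31. Of the endoplasmic reticulum list 4 of 20 rose, 7 when adjusted over the list alone, led by HERPUD1 at 0.83 and DNAJB9 at 0.59 (adjusted p = 0.00491, and adjusted p = 0.0573 with an estimated correlation). Proteasome subunits had 5 of 28 members higher, also 5 when adjusted over the list alone, with PSMB1 at 0.31 and PSMC4 at 0.25 (adjusted p = 0.000601, and adjusted p = 0.176 with an estimated correlation).

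Genes of cell division went the other way in HNE-treated control cells. Of 29 mitosis genes 27 fell, and 28 when adjusted over the list alone (camera, adjusted p = 2.69e-30), with the cyclins CCNA2 at -1.24 and CCNB1 at -1.21 and the kinesin KIF23 at -1.07. DNA replication had 21 of 29 members lower, 25 when adjusted over the list alone (adjusted p = 1.35e-13), among them the ribonucleotide reductase subunit RRM2 (-0.68), GINS1 (-0.56), CCNE1 (-0.51) and PCNA (-0.51). In the histone list 18 of 32 fell and 1 rose, against 21 and 1 when adjusted over the list alone (adjusted p = 1.1e-10), with H2BC9 at -1.21 and H1-4 at -0.99. Metallothioneins and metal transport had 5 of 9 members lower and 1 higher, and 6 and 2 when adjusted over the list alone (adjusted p = 0.0429, and adjusted p = 0.176 with an estimated correlation). MT1E fell by 0.46 and MT1X by 0.45, whereas MTF1, which drives metallothionein transcription, rose by 0.50. Without dim genes the adjusted p of this list was 0.0769.

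Apoptosis regulators changed in both directions with HNE in control cells. The survival factors BCL2L1 (-0.67 ± 0.08), BCL2 (-0.42 ± 0.07) and BCL2A1 (-0.44) fell, and the proapoptotic BID (0.32) and BCL2L11 (0.34) rose, out of 15 BCL2 family genes, with 5 lower and 2 higher when adjusted over the list alone (camera, adjusted p = 0.432). MCL1 had -0.19 ± 0.07 and was not called (adjusted p = 0.0789), but it was called without dim genes, with a trended and robust variance and with array weights (adjusted p from 0.00864 to 0.0463). Of 22 p53 targets 7 rose and 2 fell, the same counts as when adjusted over the list alone (adjusted p = 0.0206, and adjusted p = 0.056 with an estimated correlation). SESN2 rose by 0.77 and TP53INP1 by 0.72, and GADD45A fell by 0.40. Without dim genes the adjusted p of the p53 list was 0.0848.

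The fit called 8 of 23 lists upwards and 4 downwards with HNE in control cells at the preset correlation of 0.01, and 8 of these 12 calls held with an estimated correlation. The calls of BID, BCL2L11, ALDH2, PSMC4, IFIT3 and MX1 were each lost when certain single arrays were left out, and those of IFIT3 and MX1 also with a replicate block.

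**Figure D2:**
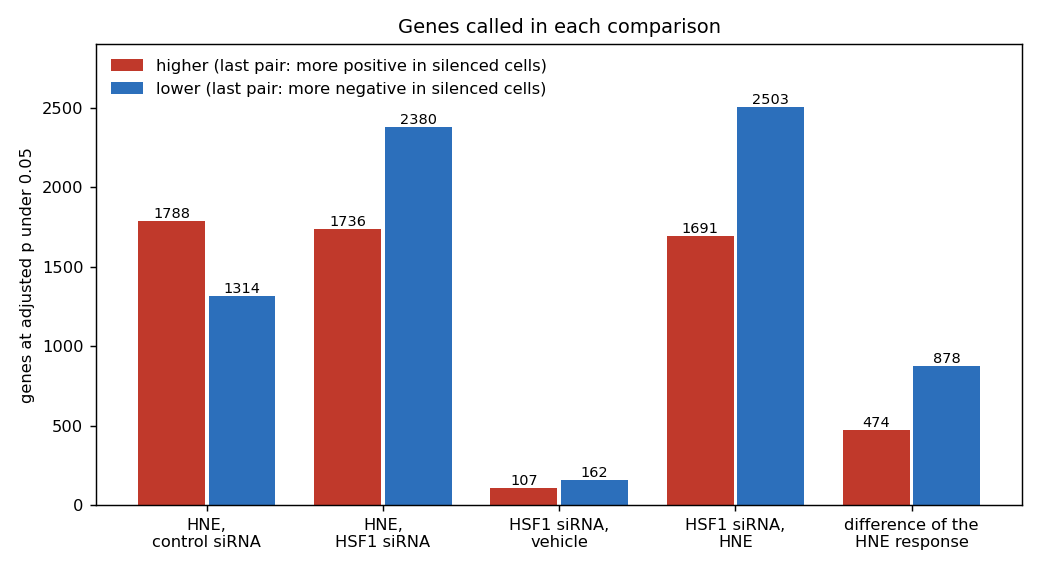
Numbers of genes called at adjusted p under 0.05 (vertical axis) in the 5 comparisons, higher in red and lower in blue, each bar over 18417 genes tested. The HSF1 siRNA changed 269 genes with vehicle and 4194 with HNE, and the last pair of bars counts the 1352 genes whose HNE response differed between silenced and control cells.

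In HSF1-silenced cells HNE again raised antioxidant genes and lowered mitotic and replication genes, while 7 of 29 chaperones and 12 of 23 immediate early genes rose. HMOX1 rose by 3.17 ± 0.08 or 9.02-fold (adjusted p = 1.53e-10), ZFAND2A by 2.68 ± 0.06 or 6.42-fold (adjusted p = 4.48e-11) and ANKRD1, an ankyrin repeat protein of the stress response in muscle, by 3.18 ± 0.15 or 9.06-fold (adjusted p = 1.34e-08). In total 4116 genes changed, 1736 higher and 2380 lower. At 2-fold or more the majority turned, with 155 of 229 genes higher and 74 lower. Further large rises were those of the deubiquitinase OTUD1 (2.76), the zinc finger genes ZNF844 (2.63), ZNF442 (2.63) and ZNF441 (2.27), EID3 (2.58), DNAJB4 (2.34), the noncoding RNA PRECSIT (2.31), LEAP2 (2.27) and SPRY2, an inhibitor of receptor tyrosine kinase signalling (2.25). H1-3 fell by 1.86, H2BC14 by 1.74, the centromere chaperone HJURP by 1.66, H2AC20 by 1.61, KIF18A by 1.5, FBXO5 by 1.48, H2BC9 by 1.40 and FASTKD2 by 1.39.

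Only 7 of the 29 heat shock chaperone genes rose with HNE in silenced cells, 7 also when adjusted over the list alone, and none fell (camera, adjusted p = 0.000175, and adjusted p = 0.152 with an estimated correlation). These were DNAJB4, DNAJB1 (1.47), HSPH1 (1.18), BAG3 (1.12), HSPA1L (1.12), HSPA6 (0.71) and HSPA4L (0.41). The 5 probe sets of HSPA1A and HSPA1B rose by 1.16 to 1.36. In the BAG family BAG2 (-0.35) and BAG5 (-0.27) fell. The NRF2 list had 12 of 29 members higher and 2 lower, the same as when adjusted over the list alone (adjusted p = 0.000175), with GCLM at 1.77, SRXN1 at 1.43, TXNRD1 at 1.01, FTL at 0.79 and SLC7A11 at 0.22. NFE2L2, which encodes NRF2, fell by 0.27. Of the ubiquitin and autophagy list 3 of 18 rose, ZFAND2A, GABARAPL1 (0.73) and MAP1LC3B (0.68), with 3 when adjusted over the list alone (adjusted p = 0.0423, and adjusted p = 0.152 with an estimated correlation), and this call ended with the arrays centred on their medians (adjusted p = 0.0667) and with single arrays left out. Cholesterol synthesis had 6 of 15 members higher, 6 when adjusted over the list alone (adjusted p = 0.00197, and adjusted p = 0.1 with an estimated correlation), with INSIG1 at 1.95 and HMGCS1 at 1.5.

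Immediate early genes, which encode rapidly induced transcription factors and phosphatases, had 12 of 23 members higher with HNE in silenced cells and 2 lower, and 15 and 2 when adjusted over the list alone (camera, adjusted p = 1.34e-05). GADD45B rose by 1.53, DUSP1 by 1.21, KLF4 by 0.60 and FOS by 0.58. In control cells the same list had 2 members higher and 6 lower, 2 and 7 when adjusted over the list alone (adjusted p = 0.0713), with IER3 at -0.71 and EGR1 at -0.46. Without control vehicle replicate 3 the list was called lower there (adjusted p = 0.037). Of 22 p53 targets 12 rose in silenced cells, and 14 rose and 1 fell when adjusted over the list alone (adjusted p = 1.34e-05), among them PLK2 (1.12), GADD45A (0.97) and TP53INP1 (0.78). PLK2 had a mean below the background level. The BH3-only genes BCL2L11 (1.67 ± 0.09) and PMAIP1 (0.79 ± 0.08), which promote apoptosis, rose in silenced cells, and BCL2L1 (-0.76), BCL2A1 (-0.64), MCL1 (-0.28) and BCL2 (-0.27) fell, with 2 higher and 4 lower when adjusted over the list alone (adjusted p = 0.896). DDIT3 rose by 1.94, PPP1R15A by 1.65 and TRIB3 by 0.95 in the ATF4 list, where 10 of 28 rose and 6 fell, against 11 and 8 when adjusted over the list alone (adjusted p = 0.0734). This list was called upwards without dim genes (adjusted p = 0.0214), after quantile normalization applied again (0.0319), after cyclic loess (0.02) and without silenced vehicle replicate 2 (0.0393).

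Mitosis had 28 of 29 members lower with HNE in silenced cells, 29 when adjusted over the list alone (camera, adjusted p = 8.26e-26), with PLK1 at -1.25 and TOP2A at -1.10. DNA replication had 24 of 29 members lower, 25 when adjusted over the list alone (adjusted p = 6.44e-15), led by MCM10 at -1.03 and MCM3 at -0.75. Of 32 histone genes 20 fell and 2 rose, against 20 and 3 when adjusted over the list alone (adjusted p = 1.87e-06, and adjusted p = 0.1 with an estimated correlation). The aldehyde metabolism list had 4 of 16 members lower, 4 when adjusted over the list alone, including GSTA4 (-0.59), a glutathione transferase that conjugates HNE, and GSTM4 (-0.37) (adjusted p = 0.0409, and adjusted p = 0.155 with an estimated correlation). That call ended without dim genes (adjusted p = 0.173) and after cyclic loess (adjusted p = 0.139). In control cells ALDH2 (0.32) was the only called gene of this list, 1 also when adjusted over the list alone (adjusted p = 0.543). Of 10 list calls with HNE in silenced cells, 5 held with an estimated correlation. The calls of BCL2, NFE2L2, NKG7, SLC7A11 and BAG5 in this comparison were each lost when certain single arrays were left out, that of SLC7A11 also with arrays centred on their medians and that of BAG5 after cyclic loess.

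**Figure D3:**
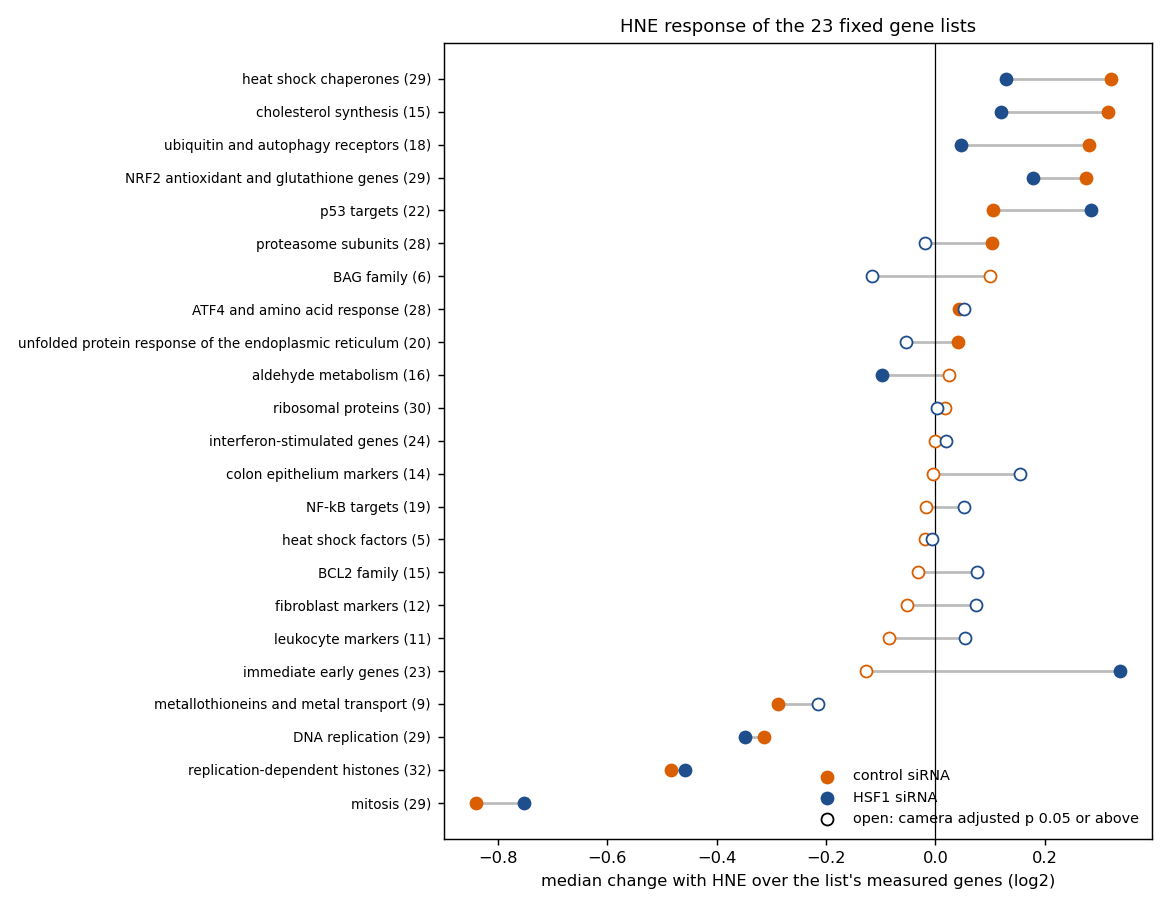
Median change with HNE (log2, horizontal axis) over the measured genes of each of the 23 fixed lists (number of genes in parentheses), in control cells (orange) and HSF1-silenced cells (blue). Filled points have a camera adjusted p under 0.05 at the preset correlation. The median of heat shock chaperones was 0.32 in control cells and 0.13 in silenced cells, and that of immediate early genes was -0.13 and 0.34.

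With vehicle, the HSF1 siRNA lowered 7 of 29 measured chaperones, and 6 of all genes changed by at least 2-fold. DNAJB1 fell by 0.87 ± 0.07 (adjusted p = 2.57e-05), HSPH1 by 0.80 ± 0.07 (adjusted p = 4.58e-05), BAG3 by 0.68 ± 0.08 (adjusted p = 0.00074) and HMOX1 by 0.54 ± 0.09 (adjusted p = 0.00753). Clusterin, an extracellular chaperone encoded by CLU, fell most, by 1.44 ± 0.10 (adjusted p = 2.07e-05). In this comparison 269 genes changed, 107 higher and 162 lower. The other large falls were those of RGS2 (-1.17), CAP2 (-1.08), TMEM156 (-0.93), DOCK4 (-0.86) and DNAJA4 (-0.79). Among the rises were ADCY10P1 (1.38), complement C5 (1.00), the hyaluronan synthase HAS2 (0.98), FILIP1L (0.89), ERRFI1 (0.79), MSL3B (0.73), KLF4 (0.71), ANKRD31 (0.69), CAMK2D (0.68), SLC17A5 (0.66), PCMTD1 (0.65) and NFKBIA, the inhibitor of NF-kB (0.65).

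Of 29 heat shock chaperones 7 were lower with the siRNA in vehicle, 11 when adjusted over the list alone, and none was higher (camera, adjusted p = 1.06e-12). The called members were DNAJB1, HSPH1, BAG3, DNAJB4 (-0.55), HSPA4L (-0.53), STIP1 (-0.50) and SERPINH1 (-0.33). Probe sets of HSPA1A and HSPA1B fell by 0.73 to 0.82. NF-kB targets had 3 of 19 members higher and 1 lower, 9 and 1 when adjusted over the list alone (adjusted p = 3.38e-05), NFKBIA, SOD2 (0.42) and ICAM1 (0.38) above and CCL20 (-0.57), whose mean was below background, beneath. BCL2L1 (-0.31, adjusted p = 0.0821), BCL2 (-0.26, adjusted p = 0.0894) and MCL1 (-0.03, adjusted p = 0.906) were not called. BCL2L1 and BCL2 were called without dim genes (adjusted p = 0.0378 and 0.0393) and with array weights (0.0286 and 0.0382), and BCL2L1 also with a trended and robust variance (0.0145) and without silenced HNE replicate 1 (0.0477). Of the 9 lists called, the heat shock and NF-kB lists held with an estimated correlation. Cholesterol synthesis, p53 targets and the ATF4 list were called upwards (adjusted p = 0.0662 each with an estimated correlation), with IDI1 (0.37) and CCNG1 (0.32) as called members, and so were ribosomal proteins (adjusted p = 0.218 with an estimated correlation). GINS2 (-0.68), PLK1 (-0.53) and H1-3 (-0.39) were the called members of the DNA replication, mitosis and histone lists, which were called downwards (adjusted p = 0.297, adjusted p = 0.527 and adjusted p = 0.288 with an estimated correlation). None of 30 ribosomal protein genes and 0 of 28 in the ATF4 list were called by limma, with 3 and 7 at an unadjusted p under 0.05. Adjusted over the list alone, 7 cholesterol, 5 p53 and 3 ATF4 list genes were higher, and 5 replication, 1 mitosis and 2 histone genes lower. The ATF4 list was no longer called without dim genes or after cyclic loess, and the mitosis list when single arrays were left out. Called genes numbered 112, 174 and 133 without control vehicle replicate 1, 2 or 3, and 121, 96 and 85 without silenced vehicle replicate 1, 2 or 3. The split of 107 higher and 162 lower turned with a trended and robust variance, which called 383 higher and 354 lower (737 genes). It was 265 and 291 without dim genes (556 genes), 318 and 358 with array weights (676 genes), and 64 and 154 with arrays centred on their medians. The calls of SERPINH1, ICAM1, IDI1, CCNG1, H1-3 and MSL3B were lost with a replicate block, and those of HMOX1, KLF4 and SOD2 when certain single arrays were left out.

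Under HNE the same siRNA difference covered many more genes, with chaperones lower and immediate early genes higher in the silenced cells. NF-kB target genes were higher too, as they were as a list with vehicle. SPRY2 was higher by 2.38 ± 0.06 or 5.21-fold (adjusted p = 2.25e-10) and LEAP2 by 2.45 ± 0.11 or 5.45-fold (adjusted p = 1.31e-08). ACTRT3 fell by 2.39 ± 0.09 (adjusted p = 4.43e-09), P4HA2 by 2.22 ± 0.07 (adjusted p = 1.3e-09) and the HSP40 gene DNAJA4 by 2.06 ± 0.06 (adjusted p = 1.25e-09). Counts were 4194 genes, 1691 higher and 2503 lower, and 161 of them reached 2-fold. Higher in silenced cells were also ANKRD1 (2.22), the SMAD corepressor SKIL (2.07), KLF10 (2.02), CASP12 (1.98), CFAP53 (1.90), RND3 (1.83), PLAC8L1 (1.8), SPDYA (1.76), BHLHE41 (1.72) and ADCY10P1 (1.69). Lower were CAP2 (-2.05), CLU (-1.93), CYP39A1 (-1.91), HSPA6 (-1.75) and the sulfide oxidase SQOR (-1.72). CASP12, SPDYA and CYP39A1 had means below the background level. The siRNA difference under HNE had a median of 0.09 over 9449 genes with a mean of up to 6, and of -0.08 over 5938 genes with a mean above 7, though 0.01 over the 849 brightest, with a mean above 10.

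Of 29 heat shock chaperones 23 were lower in HNE-treated silenced cells than in HNE-treated control cells, 25 when adjusted over the list alone, and none was higher (camera, adjusted p = 8.1e-19). HSPA4L fell by 1.44, DNAJB1 by 1.43, SERPINH1 by 1.05, BAG3 by 0.96, STIP1 by 0.88, DNAJB6 by 0.81, HSPB1 by 0.80 and HSPH1 by 0.64, and the HSPA1A and HSPA1B probe sets fell by 1.61 to 2.29. BAG2 (-0.63), BAG4 (-0.47) and BAG5 (-0.22) fell with BAG3, so 4 of 6 BAG genes were lower, 4 also when adjusted over the list alone (adjusted p = 0.0113, and adjusted p = 0.115 with an estimated correlation), and this call was lost after cyclic loess (adjusted p = 0.073). The NRF2 list had 11 of 29 members lower and 2 higher, 12 and 2 when adjusted over the list alone (adjusted p = 0.0017), with SLC7A11 at -1.47, HMOX1 at -0.62, TALDO1 at -0.53 and FTL at -0.44. Aldehyde metabolism had 6 of 16 lower, 7 when adjusted over the list alone, among them GSTM4 (-0.64) and ALDH2 (-0.46) (adjusted p = 0.00279, and adjusted p = 0.071 with an estimated correlation). DNA replication had 11 of 29 lower and 2 higher, 11 and 2 when adjusted over the list alone, GINS2 at -1.12 and MCM10 at -0.82 among them (adjusted p = 0.00171, and adjusted p = 0.301 with an estimated correlation). Proteasome subunits had 9 of 28 lower, 9 when adjusted over the list alone, with PSMA4 at -0.66 (adjusted p = 0.00353, and adjusted p = 0.301 with an estimated correlation). The median of the proteasome list was -0.078, against -0.081 over all genes with means above 7, so the intensity trend may account for its call. In the ubiquitin and autophagy list 6 of 18 were lower and 2 higher, 9 and 2 when adjusted over the list alone, ZFAND2A at -1.30 and WIPI1 at -0.61 (adjusted p = 0.00353, and adjusted p = 0.071 with an estimated correlation). Without dim genes the adjusted p was 0.0677 for the proteasome list and 0.0628 for the ubiquitin and autophagy list.

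Immediate early genes were higher in HNE-treated silenced cells for 15 of 23 members, 17 higher and 2 lower when adjusted over the list alone (camera, adjusted p = 9.97e-07), with GADD45B at 1.36, KLF4 at 1.31 and KLF6 at 1.22. NF-kB targets had 9 of 19 higher, 9 when adjusted over the list alone (adjusted p = 1.51e-05), including CCL20 (0.98), CXCL2 (0.98), NFKBIA (0.67) and SOD2 (0.57). This list was also called higher with the siRNA in vehicle. Its difference between the HNE responses was not called (camera, adjusted p = 0.143), with 1 of 19 more positive, 1 when adjusted over the list alone. Among p53 targets 8 of 22 were higher, 10 when adjusted over the list alone (adjusted p = 0.000273), with GADD45A at 1.58 and CDKN1A, the cyclin-dependent kinase inhibitor p21, at 0.79. In the BCL2 family BCL2L11 (1.33), PMAIP1 (0.72), HRK (0.43) and BBC3 (0.31) were higher and BID (-0.49) and BCL2L1 (-0.40) lower, with 4 and 2 when adjusted over the list alone (adjusted p = 0.608). Of 10 list calls in this comparison 5 held with an estimated correlation. The calls of BAG5 and BBC3 were lost with a replicate block, and that of HRK when certain single arrays were left out.

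The difference of the HNE response between silenced and control cells was tested directly. SLC7A11, ZFAND2A and 11 of 29 chaperones had a more negative response in silenced cells (chaperone list, adjusted p = 2.21e-09, and adjusted p = 0.0774 with an estimated correlation). KLF10, SPRY2, GEM and 10 of 23 immediate early genes had a more positive one (list adjusted p = 2.21e-09). KLF10 fell with HNE in control cells (7.84 ± 0.07 to 6.38 ± 0.08, SD, n = 3) and rose in silenced cells (7.45 ± 0.05 to 8.40 ± 0.13, SD, n = 3), a difference of 2.40 ± 0.11 (adjusted p = 1.01e-07). SPRY2 had no called change in control cells (-0.07, adjusted p = 0.512) and differed by 2.33 ± 0.09 (adjusted p = 2.48e-08). SLC7A11, the cystine importer, differed by -1.37 ± 0.09 (adjusted p = 1.43e-06). The responses of 1352 genes differed, 474 more positive and 878 more negative in silenced cells. The split was 65 and 64 at 2-fold or more, 516 and 666 after quantile normalization applied again, and 493 and 1270 without dim genes. Over all genes the difference had a median of 0.10 for means of up to 6 and of -0.10 for means above 7.

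Besides KLF10 and SPRY2, the most positive differences were those of LEAP2 (2.37), ANKRD1 (2.24), CASP12 (2.22), SKIL (2.17), the GTPase GEM (2.08), TRIB1 (2.01), IDI2-AS1 (1.91) and PLAC8L1 (1.86). The most negative were those of ACTRT3 (-2.32), P4HA2 (-1.88), CRYAB (-1.87), HSPA6 (-1.73), LIMD1-AS1 (-1.70), AP4B1 (-1.60), CHRNA5 (-1.46), GPX8 (-1.44), ZNF483 (-1.40) and GKAP1 (-1.39). CASP12 and CRYAB had means below the background level.

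Of 29 heat shock chaperones 11 had a more negative HNE response in silenced cells, 13 when adjusted over the list alone, and none a more positive one. They included HSPA4L (-0.90), HSPA1L (-0.98), SERPINH1 (-0.72), DNAJB6 (-0.64), HSPB1 (-0.56), DNAJB1 (-0.56, adjusted p = 0.00311) and HSPA4 (-0.49). The probe sets of HSPA1A and HSPA1B differed by -0.87 to -1.48. The difference was not called for BAG3 (-0.27 ± 0.11, adjusted p = 0.155), HMOX1 (-0.08 ± 0.12, adjusted p = 0.735), DNAJB4 (-0.08 ± 0.11, adjusted p = 0.733), HSPH1 (0.16 ± 0.09, adjusted p = 0.338), BCL2L1 (-0.09, adjusted p = 0.701), MCL1 (-0.08, adjusted p = 0.652) or BCL2 (0.15, adjusted p = 0.394). The 95% interval of the difference ran from -0.51 to -0.04 for BAG3 and from -0.34 to 0.18 for HMOX1. In the BAG family BAG2 differed by -0.53, 1 of 6 genes, and 2 differed when adjusted over the list alone (adjusted p = 0.0566). The BAG list was called downwards with arrays centred on their medians (adjusted p = 0.04) and when certain single arrays were left out.

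Immediate early genes had 10 of 23 members with a more positive HNE response in silenced cells, 12 when adjusted over the list alone, and none with a more negative one (camera, adjusted p = 2.21e-09). GADD45B differed by 1.15, DUSP6 by 0.82, EGR3 by 0.75 and EGR1 by 0.66. Ubiquitin and autophagy receptors had 3 of 18 with a more negative response, 5 when adjusted over the list alone (adjusted p = 1.23e-05), namely ZFAND2A (-1.12), GABARAPL1 (-0.79) and WIPI1 (-0.74). The p53 list had 4 of 22 more positive, and 4 more positive and 1 more negative when adjusted over the list alone, GADD45A at 1.37, CDKN1A at 0.87, PLK2 at 0.87 and PMAIP1 at 0.63 (adjusted p = 0.0168, and adjusted p = 0.0799 with an estimated correlation). The NRF2 list had 4 of 29 more negative, 4 when adjusted over the list alone, SLC7A11, FTL (-0.48), NFE2L2 (-0.40) and TALDO1 (-0.36) (adjusted p = 0.0272, and adjusted p = 0.08 with an estimated correlation), and its adjusted p was 0.0632 after cyclic loess. Proteasome subunits had 0 of 28 members called by limma and 10 at an unadjusted p under 0.05, while the list was called downwards (adjusted p = 0.00164, and adjusted p = 0.244 with an estimated correlation). The median of this list was -0.102, against -0.103 over all genes with means above 7, so the intensity trend may account for its call. Aldehyde metabolism had GSTM4 (-0.45) as its called member, 1 of 16 and 1 when adjusted over the list alone (adjusted p = 0.0168, and adjusted p = 0.156 with an estimated correlation). Without dim genes the adjusted p was 0.0518 for the aldehyde and for the proteasome list. BCL2L11 differed by 1.33 ± 0.13 (adjusted p = 5.88e-05), and with PMAIP1 it made 2 of 15 BCL2 family genes, against 3 more positive and 1 more negative when adjusted over the list alone (adjusted p = 0.143, and 0.0473 after cyclic loess). Of 7 list calls, those of the immediate early and the ubiquitin and autophagy lists held with an estimated correlation. The calls of NFE2L2 and TALDO1 were lost with a replicate block, and that of FTL when certain single arrays were left out. Without control HNE replicate 3 the count of genes was 893, and without silenced vehicle replicate 2 it was 872.

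**Figure D4:**
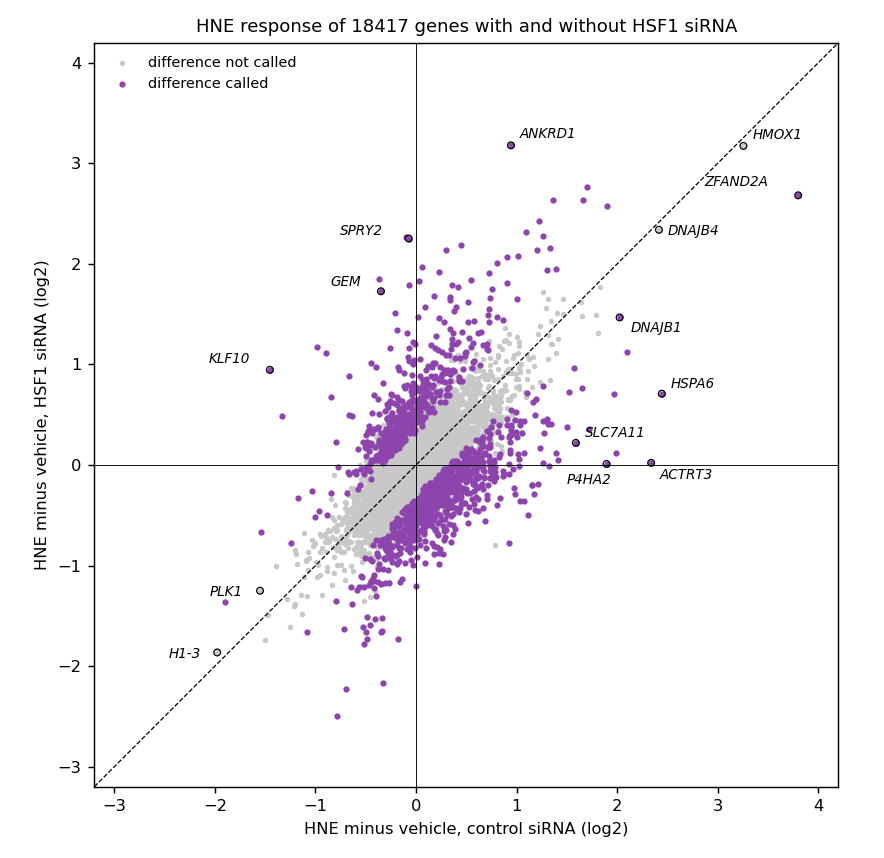
Change with HNE of 18417 genes in control cells (horizontal axis, log2) and in HSF1-silenced cells (vertical axis, log2), with the line of equal response dashed. Purple points are the 1352 genes whose difference was called, grey points the rest. HMOX1 and DNAJB4 lie close to the dashed line, SLC7A11, P4HA2 and ACTRT3 close to 0 on the vertical axis, and KLF10 on opposite sides of 0.

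The HNE responses of the control and silenced cells correlated across genes with Pearson's r = 0.51 and Spearman's rho = 0.325, and with 0.583 and 0.454 over genes above background. Genes are not independent replicates, so these values describe the arrays. In both siRNA groups 829 genes rose, HMOX1, GCLM and DNAJB4 among them, and 868 fell, PLK1 and H1-3 among them. Independent lists of these sizes would share 168.5 and 169.8 genes. The group means of these comparisons come from separate arrays, but the variance of each gene was pooled over all groups. Genes of low variance are thus called more easily in both comparisons. The independent lists also draw on all tested genes, those below background included. Some excess over independent lists can therefore arise without a shared response, and its size was not estimated. Opposite calls numbered 82 for higher in control and lower in silenced cells and 39 for the reverse, against 231.1 and 123.9 for independent lists.

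No list of cell type markers was called by camera in any of the 5 comparisons, except that colon epithelium markers were called upwards for the difference between responses when certain single arrays were left out (adjusted p from 0.0272 to 0.0456). Of 14 colon epithelium markers limma called 0 with HNE in control or silenced cells, with 2 and 3 at an unadjusted p under 0.05 (camera, adjusted p = 0.582 and 0.142), and KRT19 differed in its HNE response by 0.85 (adjusted p = 0.029), the only one of 14 (list adjusted p = 0.0667), a call lost when certain single arrays were left out. Fibroblast markers had ACTA2 higher with HNE in silenced cells (0.55), 1 of 12 (list adjusted p = 0.296), and leukocyte markers NKG7 (0.30), 1 of 11 (list adjusted p = 0.387). With HNE in control cells 0 genes of these lists were called, with 2 and 1 at an unadjusted p under 0.05 (adjusted p = 0.938 and 0.543). Interferon-stimulated genes were not called as a list, with IFIT2 (0.60), IFIT3 (0.25) and MX1 (0.27) higher with HNE in control cells, 3 of 24 and 1 when adjusted over the list alone (adjusted p = 0.503). IFIT2 and IFIT3 had means below the background level. Ribosomal protein genes had 0 of 30 called with HNE in either siRNA group by limma, with 1 and 0 at an unadjusted p under 0.05 (list adjusted p = 0.543 and 0.954). NF-kB targets with HNE had 1 of 19 higher and 3 lower in control cells, with 1 and 3 when adjusted over the list alone (adjusted p = 0.543). In silenced cells 4 were higher and 2 lower with HNE, 4 and 3 when adjusted over the list alone (adjusted p = 0.387). In the BCL2 family under HNE the siRNA difference had a median of -0.05 and a mean of 0.11, so the members on balance had no common sign. Heat shock factor genes as a list gave adjusted p = 0.924 with HNE in control cells.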

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

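Which tests came after the result was seen: those of the loess percentage, of the off-target effect and of the small nucleolar RNAs. The counts over other splits and the tests of the matched lists and left-out arrays for immediate early genes were set beforehand.

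HNE changed 121 genes in opposite directions in control and silenced cells, 39 from lower to higher and 82 from higher to lower. Independent lists would give 123.9 and 231.1. The difference itself was called for all 121, but it is computed from the same 2 responses, so that call adds no separate support. The transcription factor KLF10 differed by 2.40 (-1.45 in control cells, 0.95 in silenced cells) and the SMAD corepressor SKIL by 2.17 (-0.99 and 1.18). GEM differed by 2.08, the pseudokinase TRIB1 by 2.01, the clock-linked repressor BHLHE40 by 1.82 and the EGR corepressor NAB1 by 1.53, each lower in control cells and higher in silenced cells. IDI2 differed by 1.47 in the same direction, and AP4B1 by -1.60 in the other. In data outside the gene-level comparisons, 434 of 12083 probe sets with no listed symbol were called with HNE in control cells, 261 of them higher, and so were 180 of 1754 with several symbols, 98 of them higher.

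For the comparisons of 3 against 3 arrays, 10 splits are too few for a share under 0.05. The real split gave 3102 genes for HNE in control cells, 4116 for HNE in silenced cells, 269 for the siRNA with vehicle and 4194 for the siRNA with HNE, the highest other split gave 0 in each case, and 1 of 10 splits, the real one, gave as many. For the difference between the HNE responses, 8 of 100 exchanges of siRNA labels within treatments, drawn from 200 and counting the real one, gave at least the real 1352 genes, and the highest other gave 1995, so chance cannot be excluded by this count. Of the 100 exchanges, 11 kept the HNE-treated arrays apart by siRNA, 8 of these gave as many genes and the lowest gave 973. The 89 that mixed the HNE-treated arrays gave 0 genes at most, but mixing puts their siRNA difference into the spread, so this does not bear on chance. Exchanges of vehicle arrays alone left 973 genes or more. They leave in place the contrast among the 6 HNE-treated arrays, on which much of the count can rest.

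More genes were lower than higher in HNE-treated silenced cells than in HNE-treated control cells, 59.7% of those called. An array-wide trend with intensity, left after the authors' normalization, may add to this, since in these arrays genes with means of up to 6 sat higher and genes with means of 7 to 10 lower. After cyclic loess 58.5% were lower, and 57.7% to 60.2% with single arrays left out. Loess shrank the trend but left its sign. The median difference went from 0.085 to 0.021 for means of up to 6 and from -0.081 to -0.033 for means above 7. The share moved little while the trend shrank, but with part of the trend left this cannot exclude it as a cause. The share still depends on the scaling, with 54% after quantile normalization applied again and 69.6% with arrays centred on their medians. An effect of silencing under HNE stays open. So does a batch or a difference in array quality among the HNE-treated silenced arrays, for which the labels give nothing to test. The upper quartile of the values was 7.28 to 7.34 in these arrays and 7.35 to 7.45 in the arrays of the other groups.

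Of 23 immediate early genes 12 were called higher and 2 lower with HNE in silenced cells, against 2 and 6 in control cells, with a median difference of 0.42. Among 10000 lists matched on mean level this lay at percentile 100, above the upper end of their central 95%, 0.10, and their highest value, 0.21, which argues against the intensity trend, and it was 0.47 after cyclic loess. The lowest value without 1 array was 0.37, which argues against a single deviating array. Leaving out 1 array cannot address a batch or handling effect shared by all HNE-treated silenced arrays, which stays open. An off-target effect of the siRNA could also raise these genes: the list's median with the siRNA in vehicle was -0.049, but with no second siRNA against HSF1 the effect of losing HSF1 and an effect of this siRNA sequence under HNE cannot be told apart. That loss of HSF1 allows stress signalling to induce these genes under HNE is a hypothesis that these data leave open.

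C/D box small nucleolar RNAs above background, 59 in number, had a median of -0.60 with HNE in silenced cells and -0.30 in control cells, with 36 called lower and 6 higher in silenced cells. Over all 115 measured the medians were -0.106 and -0.103, and the camera call of the class (adjusted p = 1.09e-06 and 0.00292) was lost with an estimated correlation (adjusted p = 0.108 and 0.4). An equally lower recovery of all small RNAs is argued against by the small Cajal body RNAs, 11 above background, whose median was higher by 0.90 (permutation p = 0.0132). H/ACA box RNAs, 42 above background, had a median of -0.09 with HNE in silenced cells, with 14 called lower and 5 higher. A recovery that differs with length is not addressed by these classes, whose lengths were not compared. The 20 measured genes around 27 of the C/D box RNAs, taken as hosts by position without regard to strand, had a median of -0.028 (bootstrap interval -0.10 to -0.01). The median of those 27 RNAs was -0.47. They include the pseudogenes SNORD13P1, SNORD13P2 and SNORD13P3, for which the gene around need not be a host. Host transcript levels thus fell less, with 3 hosts called lower. Levels do not measure transcription of the hosts, so a fall in host transcription stays open. A lower recovery of shorter RNAs may be a cause. Over C/D box RNAs of 60 to 205 bases the shorter ones had the more negative change, with Spearman's rho of 0.346 (permutation p = 0.00733). Both permutation tests treat RNAs measured on the same arrays as independent. The RNA passed an RNeasy column and was amplified before labelling, and the retention of RNAs this short was not measured. The values may thus not follow the levels of these RNAs in the cells. A biological change stays open, untested.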

How the results depend on the processing

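Cyclic loess was the setting chosen after the data were seen. With a 2-fold threshold the counts of called genes were 139, 229, 6, 161 and 129 for HNE in control cells, HNE in silenced cells, the siRNA with vehicle, the siRNA with HNE and the difference between responses, a fall that follows from the stricter threshold, and for HNE in silenced cells the share of lower genes went from 57.8% to 32.3%, and for the difference from 64.9% to 49.6%. The siRNA count with vehicle, 269, was 140 with a replicate block, 556 without dim genes, 737 with a trended and robust variance and 676 with array weights. Of its calls 60.2% were lower, against 48% with the trended and robust variance, where the majority turned, 52.3% without dim genes, 53% with array weights and 70.6% with arrays centred on their medians. The cause was not tested. The correlation of the HNE responses, 0.51, was 0.583 without dim genes, 0.369 over all probe sets, 0.54 after quantile normalization applied again and 0.547 after cyclic loess, and the cause was not tested. Single arrays left out gave 2374 to 3199 genes for HNE in control cells, 3202 to 4159 for HNE in silenced cells, 85 to 328 for the siRNA with vehicle, 2902 to 4431 for the siRNA with HNE and 872 to 1635 for the difference. They gave a correlation of 0.446 to 0.531 and an HSF1 change of -0.607 to -0.466 with vehicle and -0.544 to -0.413 with HNE. The counts stayed within 1.5 times under the other settings. Of 48 list calls 26 were lost with an estimated correlation, 11 without dim genes, 6 after cyclic loess and 4 after quantile normalization applied again, while 0, 3, 4 and 2 calls were gained, and none reversed. With fry, which does not compare a list with other genes, 25 calls were gained and 2 lost. Replicate numbers did not pair the arrays: residuals of 18 same-number pairs correlated between -0.251 and 0.245, and 2 were above 0.1. Pairs with different numbers correlated between -0.223 and 0.208. Control vehicle replicate 3, control HNE replicate 2 and silenced HNE replicate 2 correlated with each other by 0.198 to 0.245. They thus shared a deviation that the labels do not name. As signal over background limits these data, 62.8% of genes lay above the olfactory receptor level.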

Other observations

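The test of zinc finger genes and the U6atac RNA were chosen after the values had been seen. Zinc finger genes with symbols starting with ZNF, many of them transcriptional repressors of the KRAB class, were more often higher than lower with HNE. Of 494 measured, 147 were higher and 17 lower in control cells (camera over 4 symbol classes, adjusted p = 8.44e-10, and adjusted p = 0.0199 with an estimated correlation), and 150 were higher and 49 lower in silenced cells (adjusted p = 9.92e-06, and adjusted p = 0.0992 with an estimated correlation). ZNF844 rose by 1.66 and 2.63, ZNF442 by 1.37 and 2.63 and ZNF441 by 1.26 and 2.27 in control and silenced cells. The HNE response was more positive in silenced cells for 29 of the 494 genes and more negative for 36. A camera test of that difference over the class gave an adjusted p = 0.467. RNU6ATAC, the U6atac RNA of the minor spliceosome, rose with HNE by 1.22 in control cells and 2.43 in silenced cells. It was higher with the siRNA by 1.43 in vehicle and 2.64 under HNE, and differed in its response by 1.21. Whether a difference in the recovery of small RNAs, on the RNeasy column or in amplification, adds to these values was not tested.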
